A study of Sus scrofa with 56 samples.

How the data were processed

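Liver (24 pigs) and testis (32 pigs) of male crossbred pigs were profiled with 1 RNA sequencing library per tissue and pig. Per the labels' protocols, RNA was extracted with a column kit and made into libraries with a stranded mRNA kit. The deposited files hold raw read counts per Ensembl gene, 1 file per library, with 25322 genes and 5 summary rows of the counting tool. Per the submitters' processing notes, Trimmomatic 0.33, cutadapt 1.8.1, STAR, SAMtools 1.3.1 and HTSeq 0.6.0 were used by the authors, with the role and order of each not stated. The version of STAR, the genome build, the gene annotation and the strand setting of the counting are not given in the sources used here, so no coordinates are given. The kit keeps the strand, but since the counting setting is not stated, reads of overlapping or antisense genes, and of near-identical copies in multigene families such as the cytochrome P450s, sulphotransferases and ribosomal proteins, could be divided wrongly or lost, and these genes are uncertain.

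The 5 summary rows name no gene and stayed out of library sizes and tests. Reads outside any gene made up 11.1% to 62.1% of all counted reads in liver and 20.6% to 39.6% in testis. Reads counted as ambiguous between genes came to 0.320% to 0.764% of the reads in genes in liver and 0.0360% to 0.0890% in testis. Symbols came from a table that pairs Ensembl gene IDs with names: 11804 IDs had a symbol and 13518 had none, and a gene without a symbol is given by its ID. Reads in genes ranged from 7202297 to 26911699 per liver library and from 1855174 to 20349500 per testis library, so genes of low expression are measured with less error in liver and in the 8 deeper testis libraries.

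Groups were taken from the labels: High or Low ASI by control or chicory diet, 4 groups per tissue. All comparisons, gene lists, named genes and alternatives were fixed before the data were examined, unless said otherwise. Counts were tested with edgeR 4.0.16 (R 4.3.3): TMM normalization, the filterByExpr filter with the groups of the tissue, robust quasi-likelihood fits and F tests, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. This gave 12714 genes in testis, 12648 in liver and 15987 in the 48 libraries of the 24 pigs with both tissues. Testis fits had terms for ASI, diet and library set, and liver fits for ASI and diet. The fit between tissues had terms for tissue, ASI and diet, and those of the ASI and diet differences also had the interactions of tissue with ASI and with diet, without a set term. The fits on androstenone used log2 of the label's value plus 0.5 mg/kg, and those on breeding value and skatole used diet, and in testis library set, beside the trait. Values in CPM, counts scaled to the same library size, were computed here from the deposited counts with TMM library sizes, and standard errors of fold changes from the fitted coefficient and its F statistic. Pigs are the replicates, from 14 sows and 12 sire families, where pigs with the same sire EBV were taken as 1 family.

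Of 971 members of 39 gene lists fixed beforehand, 626 matched a symbol; 25 lists were meant for testis and 32 for liver, and lists with 5 or more measured members were tested (22 in testis, 31 in liver, 38 across tissues). The test was camera of limma 3.58.1 with a preset correlation between genes of 0.01, with adjustment over the lists of the tissue, and it was repeated with an estimated correlation and with fry. Camera compares a list with the other genes, while fry asks whether its members move on balance in 1 direction. Of the calls with the preset correlation, those that held with an estimated correlation were the cholesterol list between ASI groups in testis and 10 lists between tissues.

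Genes were named by a fixed rule: per comparison, up to 10 genes with a symbol and the smallest p past the threshold in each direction, or the 3 smallest p in each direction given as values if none passed, the 4 members with the smallest p of each list called, and a set of steroid and skatole enzymes. The text prints part of them. Called genes without a symbol were added after their values were seen. STAR (the gene), HSD3B1, SRD5A2, SULT2A1, SULT2B1, CYP2C49, CYP3A29, SULT1A1 and HSD17B2 of that set had no match under their symbol and are not given.

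Traits came from the labels, 1 value per pig, with 3 carcass weights listed as 0 taken as missing. Means were compared by 2-sided permutation tests (100000 resamples) and skatole above 0 by Fisher's exact test. Both took single pigs as independent, without regard to sow or sire family. The planned trait tests numbered 6; pooling them as 1 family, and the 2 tests of breeding value, were chosen after values were seen, so adjusted p is given over both families. Over the 6 permutation tests alone, those of breeding value included, carcass weight had adjusted p = 0.0780. For the 6 testis genes called against a trait, slopes of log2 CPM were computed by least squares within each library set, without a test.

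Pairing comes from the pig number in the labels, since liver and testis of a number are from the same animal. Checked over 10452 genes, deviations from the group mean in the 2 tissues of a pig correlated with a median r of 0.0195 (-0.200 to 0.379 over 24 pigs), against -0.00255 for different pigs; 8 pigs were above 0.1 and 4 correlated best with their own other tissue. The pig number was a block in an alternative fit.

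Alternatives were other size factors (RLE), no filter on low counts, the Wald test of DESeq2 1.42.0, each pig left out, fits without the library set term or on 1 set only, sequencing lane or sire family as a factor, the sow as a random block (limma voom), 2 surrogate variables (sva 3.50.0), and other scales of androstenone. After the data were examined, fits were added without the testes of pigs 5983 and 5990, without the liver of pig 7863 and, between tissues, without pigs 5990 and 7863 and with the testis library set as a term. The definition of the 75 liver-restricted genes (mean above 200 CPM in liver and a ratio above 2000 to the mean of the unnumbered testis libraries), the limit of 3 reads for the gene seen in part of the pigs, and the spread of the cholesterol list median from leaving out each library were also chosen after the data were examined.

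The procedure was tested on simulated counts with 50 genes changed at each of 4 fold sizes. Of genes changed 1.5-fold and 2-fold, 52% and 84% were called between ASI groups in testis (12568 genes), 26% and 74% in liver (12480 genes), 96% and 100% per log2 unit of androstenone in testis (12601 genes), 6% and 18% for the interaction in liver (12460 genes) and 10% and 32% for the diet difference between tissues (15838 genes). Unchanged genes made up 2.91%, 3.97%, 5.71%, 4.55% and 2.22% of the calls. A simulated shift of the 20 cholesterol genes by 0.25 (log2) between ASI groups in testis gave adjusted p = 9.53e-08 in camera and 1.35e-05 with an estimated correlation, and 1 other of the 22 lists was called. Simulated genes were drawn independently of each other, without the correlation between genes of real samples. All changed genes were also present at once. Where fewer genes change, the adjustment is stricter and the shares called would be lower. The shares called, the shares of unchanged genes and the list p need therefore not hold for the real counts.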

Results

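Gene expression was measured by RNA sequencing in liver and testis of 32 male Danish pigs, crosses of Duroc with Landrace/Yorkshire. The pigs differed in boar taint, the off-flavour of pork from entire males that androstenone, skatole and indole in fat give, and the labels placed each pig in a High or a Low ASI group (ASI for the 3 compounds). Some of the pigs had received chicory as a 15% additive before slaughter. The testis was sequenced in all 32 pigs and the liver in 24 of them, 56 libraries in all. Liver comprised 7 High ASI control, 6 High ASI chicory, 5 Low ASI control and 6 Low ASI chicory pigs, and testis 10, 7, 7 and 8 pigs in the same order. Liver libraries held 7202297 to 26911699 reads in genes and testis libraries 1855174 to 20349500.

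The testis libraries fell into 2 sets by their labels. In 8 of them, 6 High and 2 Low ASI, the label carries a library number and the depth was 10585625 to 20349500 reads. The other 24, 11 High and 13 Low ASI, carry none and held 1855174 to 5993637 reads. Mitochondrial transcripts took 5.41% to 15.8% of reads in the numbered libraries (median 7.33%) and 1.56% to 17.5% in the unnumbered ones (median 2.59%). The set was a term in the main fits on testis alone, while the main fits across both tissues had terms for tissue, ASI and diet and none for the set. Spermatid genes took 0.529% of the reads of the Low ASI chicory testis of pig 5983 and 3.42% to 4.92% in the other testes of its group. Transcripts of 75 liver-restricted genes stood at 0.995% of their liver level in the High ASI control testis of pig 5990 and at 0.00322% to 0.0379% in the rest of its group. These genes were picked as low in the unnumbered libraries, so low levels there are built in. The numbered libraries other than that of pig 5990 stood at 0.00572% to 0.0379%. In the High ASI control liver of pig 7863, 2.01 reads fell outside genes for each read within a gene, against 0.206 to 0.394 in the other livers of its group.

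**Figure D1:**
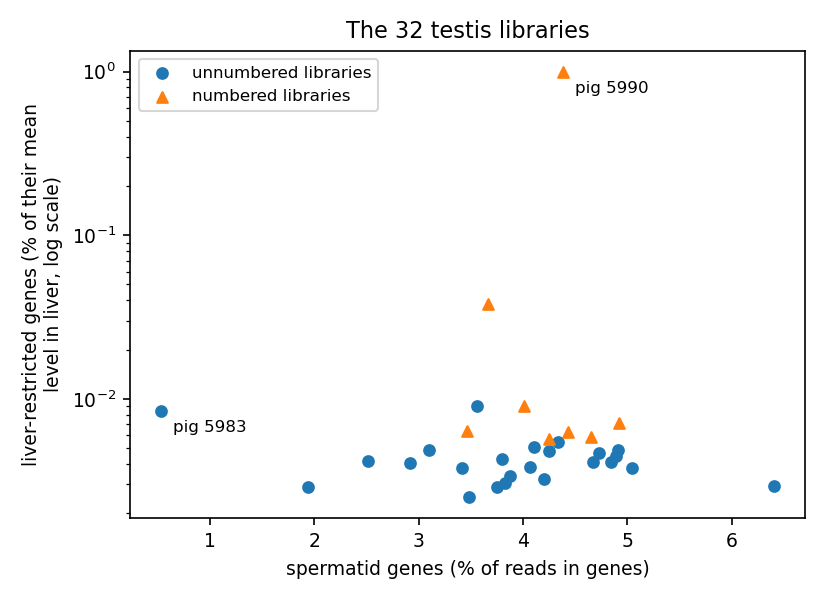
Each point is 1 of the 32 testis libraries, placed by the percent of its reads in spermatid genes (x axis) and by the mean level of 75 liver-restricted genes as a percent of their level in liver (y axis, log scale), with the symbol giving the library set. Pig 5990 stands at 0.995% of the liver level and pig 5983 at 0.529% spermatid reads, apart from the other libraries.

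Androstenone, a pheromone steroid of the testis, was part of how the ASI groups were made, and averaged 2.59 ± 1.99 mg/kg (SD, n = 17) in High and 0.504 ± 0.415 mg/kg (SD, n = 15) in Low ASI pigs (2-sided permutation p = 4e-05). With chicory it averaged 1.40 ± 1.60 mg/kg (SD, n = 15) and with the control diet 1.80 ± 1.99 mg/kg (SD, n = 17), a difference of -0.396 mg/kg within the spread between pigs (permutation p = 0.559). Skatole, a product of gut bacteria that the liver clears, was above 0 in 2 of 15 chicory pigs and 9 of 17 control pigs, and in 9 of 17 High and 2 of 15 Low ASI pigs (Fisher's exact p = 0.0278 for each). Skatole, like androstenone, is among the compounds the ASI groups are named for, so its test between those groups is partly fixed by how they were made. Carcasses of High ASI pigs weighed 91.7 ± 5.56 kg (SD, n = 15) and those of Low ASI pigs 87.0 ± 5.10 kg (SD, n = 14; permutation p = 0.0260), while the diets differed by -1.03 kg (permutation p = 0.640). All the trait tests took single pigs as independent, although many shared a sow or sire family. The skatole and carcass differences had adjusted p = 0.0417 over the 6 trait tests planned and 0.0556 over 8 with 2 tests added, so whether they pass depends on the family of tests. Both families also count the ASI tests of androstenone and skatole, partly fixed by how the groups were made. Their small p lowers the adjusted p of the carcass test and of skatole between diets. The 2 tests not planned compared the sire's estimated breeding value (EBV) for androstenone, which averaged 0.0612 ± 0.25 (SD, n = 17) in High and -0.111 ± 0.254 (SD, n = 15) in Low ASI pigs (permutation p = 0.0634). Pigs of a sire family share this value, so the SD and p count the same family value more than once. With skatole counted as above 0.083 mg/kg, the median of the values above 0, Fisher's exact p was 0.338 for both contrasts, which neither family of tests counts.

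In testis, genes of cholesterol biosynthesis, the pathway that feeds steroid synthesis, were higher in High than in Low ASI pigs as a group. All 20 measured members had a positive log2 fold change, with a median of 0.23. HMGCS1 (ENSSSCG00000016872), which makes the HMG-CoA from which sterols are built, had 0.39 ± 0.15 (log2, SE), SQLE, the squalene epoxidase, 0.22 ± 0.09 and FDPS, which makes farnesyl diphosphate, 0.21 ± 0.10. The list passed the camera test (adjusted p = 6.13e-13) and kept its call with an estimated correlation (adjusted p = 0.0310), but missed the threshold in fry, which asks whether the members move on balance 1 way (adjusted p = 0.0594). Of its members 4 had an unadjusted p under 0.05, 0 were called over all genes and 0 when adjusted over the list alone. Leaving out 1 library at a time moved the list median between 0.19 and 0.32, and the jackknife SE from these fits was 0.143. Random regrouping of the pigs within sire families also gave medians as large, so chance cannot be excluded. Markers of Leydig cells, which make the steroids, also passed camera: 7 of 11 were positive with a median of 0.37 (camera adjusted p = 1.57e-04; adjusted p = 0.464 with an estimated correlation). Without the library set term their median was 0.16 (camera adjusted p = 0.104), and in the unnumbered libraries 0.24. Among them were VCAM1 with 0.69 ± 0.24, LHCGR, the luteinising hormone receptor, with 0.65 ± 0.34, and CYP17A1, the 17-alpha-hydroxylase, with 0.61 ± 0.27.

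Other lists passed camera between the ASI groups in testis but lost the call with an estimated correlation. Genes of spermatids, the maturing germ cells, were positive in 24 of 24 members with a median of 0.19 (camera adjusted p = 1.59e-07; adjusted p = 0.515 with an estimated correlation), with PRM2, a protamine, at 0.36 ± 0.27 (log2, SE) and GAPDHS at 0.22 ± 0.19. With 2 surrogate variables their median was 0.058 and the call was lost (camera adjusted p = 0.232). Without the testes of pig 5983, the Low ASI pig low in spermatid reads, and pig 5990 it was 0.13. Genes of the cytosolic ribosome were negative in 16 of 17 members with a median of -0.22 (1.59e-07 and 0.464), with RPS16 at -0.30 ± 0.15 and a median of -0.11 with 2 surrogate variables. Steroid synthesis enzymes were positive in 7 of 11 members with a median of 0.16 (0.0105 and 0.515). SRD5A1 (ENSSSCG00000017103), the 5-alpha-reductase that makes androstenone and dihydrotestosterone, stood at 0.53 ± 0.20, CYP11A1, which splits the cholesterol side chain, at 0.42 ± 0.26, INSL3, a Leydig cell hormone, at 0.45 ± 0.28, CYB5A, a cytochrome b5 that helps CYP17A1 make androgens and androstenone precursors, at 0.16 ± 0.20 and HSD17B3, which makes testosterone, at -0.20 ± 0.20. The steroid list lost its call without the library set term (median 0.13, camera adjusted p = 0.588) and in the unnumbered libraries (0.15, 0.312), while its median was 0.27 with sire family as a factor (0.00633). In these 3 lists and the Leydig list 0 members passed when adjusted over the list alone. Among single genes edgeR called 0 of 12714 (smallest adjusted p = 0.994) and DESeq2 0, with 275 at an unadjusted p under 0.05 in edgeR. The smallest p on the positive side belonged to CYP4B1 with 0.94 ± 0.27, PC, the pyruvate carboxylase, with 0.41 ± 0.13 and SLC46A3 with 0.65 ± 0.20, and on the negative side to FBXL16 with -0.77 ± 0.22, NPR1 with -0.66 ± 0.19 and EPHA7 with -0.82 ± 0.27.

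The relation of testis genes to the androstenone measured in each pig, the trait in the series title, was tested as a slope on log2 of androstenone plus 0.5 mg/kg. Both CYP4B1 (ENSSSCG00000003894), a cytochrome P450, and SRD5A1 rose with androstenone, by 0.63 ± 0.11 (log2 per log2 unit, SE; adjusted p = 0.0200) and 0.40 ± 0.08 (adjusted p = 0.0373) in edgeR's quasi-likelihood test. CYP4B1 averaged 24.9 ± 11.9 CPM (SD, n = 17) in High and 14.9 ± 8.95 CPM (SD, n = 15) in Low ASI testis and was above the Low ASI median in 14 of 17 High ASI pigs. SRD5A1 averaged 64.3 ± 28.9 and 45.9 ± 18.7 CPM and was above it in 13 of 17. Of 12714 genes 4 were called, 3 positive and 1 negative. The others have no symbol, ENSSSCG00000020872 with 1.23 ± 0.24 (adjusted p = 0.0373) and ENSSSCG00000021574 with -2.76 ± 0.44 (adjusted p = 0.00362). The latter had more than 3 reads in 8 of 32 testis libraries, 2 High and 6 Low ASI, and 0 reads in 21, so its slope compares pigs with and without it. Within the 24 unnumbered libraries the least-squares slope of log2 CPM was 0.72 ± 0.14 (SE) for CYP4B1 and 0.42 ± 0.09 for SRD5A1, and within the 8 numbered ones 0.83 ± 0.34 and 0.30 ± 0.25. For ENSSSCG00000020872 it was 1.29 ± 0.27 and 1.60 ± 0.67, and for ENSSSCG00000021574 -1.72 ± 0.36 and -1.30 ± 1.06, in the numbered ones -0.41 ± 1.80 without the 2 pigs farthest from the median androstenone. All 4 genes were picked for this slope in the same pigs, so the values within the sets are given without a test. Fitted on the unnumbered libraries alone, edgeR called ENSSSCG00000021574 but not CYP4B1 and SRD5A1 (adjusted p = 0.155 and 0.106). With sire family as a factor the slopes of CYP4B1 and SRD5A1 were 0.64 and 0.53 and edgeR called 0 genes. EdgeR also called 0 without the library set term and without pig 5995, 8080 or 8086.

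**Figure D2:**
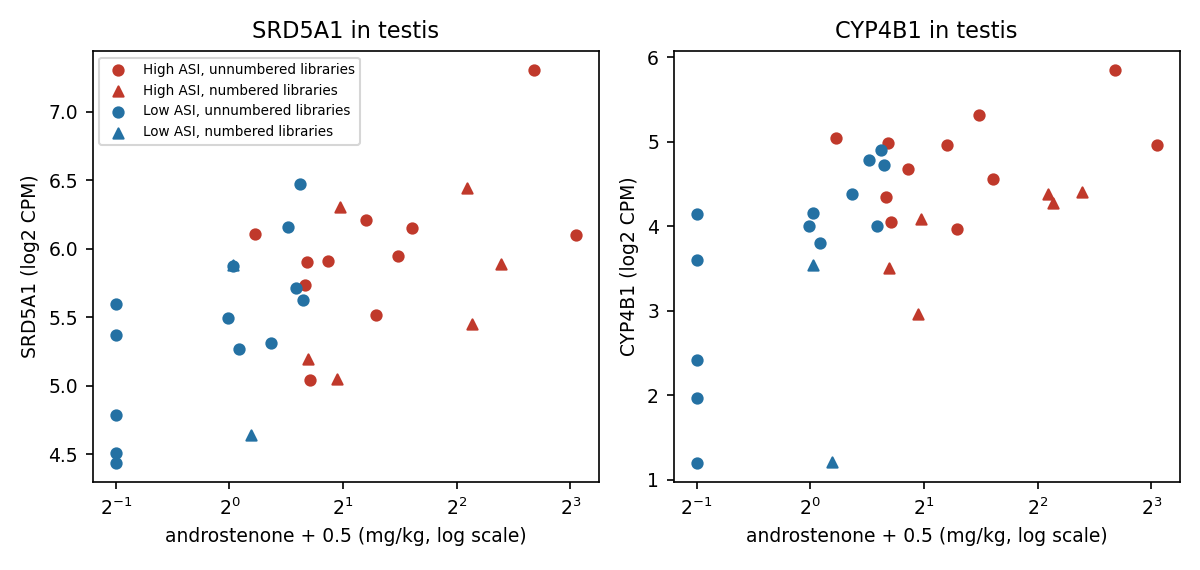
Expression in testis of the 2 genes with a symbol that were called against androstenone, 1 panel per gene: log2 CPM against androstenone plus 0.5 mg/kg (log scale), 1 point per pig, with colour for the ASI group and symbol for the library set. Within the unnumbered libraries the slope was 0.72 for CYP4B1 and 0.42 for SRD5A1 (log2 per log2 unit).

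Cholesterol biosynthesis genes were also positive against androstenone, in 19 of 20 members with a median of 0.10 (camera adjusted p = 2.43e-07; adjusted p = 0.294 with an estimated correlation), with FDPS at 0.14 ± 0.05 (log2 per log2 unit, SE) and LSS, the lanosterol synthase, at 0.20 ± 0.09. Steroid synthesis enzymes were positive in 8 of 11 members (median 0.14; 0.00387 and 0.634), with 1 gene, SRD5A1, called over all genes and over the list alone, CYP17A1 at 0.30 ± 0.14 and HSD17B3 at -0.20 ± 0.09. Leydig cell markers were positive in 8 of 11 (median 0.23; 0.00635 and 0.640), 1 of them past the threshold when adjusted over the list alone, VCAM1 at 0.38 ± 0.11. Without the library set term the medians of both the steroid and the Leydig list were 0.082 and neither passed (camera adjusted p = 0.417 and 0.309). With sire family as a factor the medians were larger, 0.24 for the steroid, 0.43 for the Leydig and 0.19 for the cholesterol list (1.18e-06, 1.50e-08 and 1.35e-08). Spermatid genes were positive in 23 of 24 (median 0.12; 6.72e-05 and 0.729), with ODF2, a protein of the sperm tail, at 0.15 ± 0.07. Their median was 0.044 with sire family as a factor and 0.046 with 2 surrogate variables, and the call was lost in both (camera adjusted p = 0.104 and 0.401). Genes of the mitochondrial genome were positive in 11 of 13 (median 0.08; 0.00166 and 0.729), a median that turned to -0.039 with sire family as a factor (camera adjusted p = 0.622) and was 0.28 without the set term (2.19e-05) and 0.14 without the testes of pigs 5983 and 5990 (5.00e-06). Markers of spermatogonia, the germ line stem and progenitor cells, were negative in 8 of 8 (median -0.13; 0.0153 and 0.294), with KIT at -0.21 ± 0.12, and lost the call without the set term (-0.15, camera adjusted p = 0.0533) and in the unnumbered libraries (-0.13, 0.126) but not with sire family (-0.20, 0.0233). In the last 3 and in the cholesterol list 0 members passed when adjusted over the list alone. With an estimated correlation 0 of the 22 lists passed in this comparison.

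The sire's breeding value for androstenone, 1 value per sire family of 12, was tested as a slope over pigs, and 2 testis genes passed. PHOSPHO2 (ENSSSCG00000015936), a phosphatase, rose with it by 1.61 ± 0.30 (log2 per unit of EBV, SE; adjusted p = 0.0334) and ABCB10 (ENSSSCG00000010188), a mitochondrial transporter of red cell haem synthesis, fell by 2.15 on the log2 scale (SE 0.37; adjusted p = 0.0197, edgeR). Within the 24 unnumbered libraries the least-squares slope of log2 CPM was 1.31 ± 0.40 (SE) for PHOSPHO2 and -1.99 ± 0.48 for ABCB10, and within the 8 numbered ones 2.24 ± 0.24 and -1.71 ± 0.86. In the numbered ones the slope of ABCB10 turned to 0.43 ± 0.99 without the 2 pigs farthest from the median EBV. Both genes were picked for this slope in the same pigs, so the values within the sets are given without a test. Spermatid genes were positive in 21 of 24 members with a median of 0.55 (camera adjusted p = 4.6e-04; adjusted p = 0.995 with an estimated correlation), 1 of them past the threshold when adjusted over the list alone, with PRM2 at 1.53 ± 0.46 and SPATA3 at 0.96 ± 0.35, and their median was 0.31 with 2 surrogate variables. Fibroblast and matrix genes were negative in 16 of 18 (median -0.61; 0.0133 and 0.995; 0 over the list alone), with SPARC at -1.41 ± 0.56. In the unnumbered libraries their median was -0.055 and the list turned in its test, and it lost the call without the set term (-0.65, camera adjusted p = 0.0677) and with 2 surrogate variables (-0.24, 0.0618). In the unnumbered libraries alone edgeR called 0 genes, as without pig 7863, 8080 or 8095. DESeq2 called 15 in all libraries. With the sow as a block PHOSPHO2 and ABCB10 had adjusted p = 0.0504 and 0.240, and 11 of 100 orders of the family values gave 2 or more calls.

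In testis, 15 chicory pigs were compared with 17 control pigs. Endothelial markers were negative in 9 of 9 members with a median of -0.17 (camera adjusted p = 5.95e-05; adjusted p = 0.331 with an estimated correlation), LYVE1, a receptor of lymph vessels, at -0.61 ± 0.24 (log2, SE). Cholesterol biosynthesis genes were negative in 14 of 20 members with a median of -0.08 (0.0204 and 0.741), with INSIG1, which holds back sterol synthesis, at -0.34 ± 0.15. Sulphotransferase and glucuronidation genes were negative in 5 of 5 (median -0.12; 0.0204 and 0.580), with SULT1A3 at -0.34 ± 0.31. Leydig cell markers were negative in 8 of 11 (median -0.25; 0.0259 and 0.821), with LHCGR at -0.56 ± 0.33. Iron, haem and glutathione genes were negative in 8 of 16 (median -0.03; 0.0360 and 0.580), with FECH, the last enzyme of haem synthesis, at -0.30 ± 0.14. In all 5 lists 0 members passed when adjusted over the list alone. The number of lists that passed was 3 without the set term, 2 in the unnumbered libraries and 8 without the testes of pigs 5983 and 5990. In the unnumbered libraries the endothelial, sulphotransferase, Leydig and iron lists lost their calls (medians -0.16, -0.13, -0.19 and -0.034, camera adjusted p = 0.102, 0.232, 0.129 and 0.355). Without the set term the cholesterol, Leydig and iron lists lost theirs (-0.052, -0.22 and -0.0075, with 0.0807, 0.0815 and 0.0959). With sire family the sulphotransferase, Leydig and iron lists did (-0.097, -0.18 and -0.066, with 0.229, 0.268 and 0.0673), and the iron list also without the testes of pigs 5983 and 5990 (-0.065, 0.136). The cholesterol median was -0.12 with sire family (0.00396) and the iron median -0.070 with 2 surrogate variables (0.0367). Of 12714 genes edgeR and DESeq2 called 0, and 126 had an unadjusted p under 0.05 in edgeR, led by PNCK (0.58 ± 0.19), OOEP (1.06 ± 0.35) and HEY2 (0.73 ± 0.27) on the positive side and FAM200A (-0.48 ± 0.17) and EXOSC9 (-0.86 ± 0.31) on the negative side.

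Whether the diet difference in testis depended on the ASI group was tested as an interaction, positive where chicory minus control was larger in High ASI pigs. Spermatid genes were positive in 24 of 24 members with a median of 0.29 (camera adjusted p = 6.78e-06; adjusted p = 0.922 with an estimated correlation), PRM2 at 1.28 ± 0.51 (log2, SE). Markers of Sertoli cells, the nurse cells of the germ line, were negative in 10 of 12 (median -0.59; 0.0301 and 0.922), with CLU at -1.03 ± 0.35 and FSHR, the receptor of follicle-stimulating hormone, at -1.31 ± 0.59. Genes of the mitochondrial genome were negative in 12 of 13 (median -0.68; 0.0430 and 0.922), with ND6 at -1.24 ± 0.68. The mitochondrial median turned to 0.27 without the set term, 0.11 without the testes of pigs 5983 and 5990 and 0.14 with sire family, and mitochondrial transcripts took 14.4%, 17.5% and 15.8% of reads in the testes of pigs 5990, 5983 and 5982. The libraries of pigs 5990 and 5982 are of the numbered set, where the share was higher (median 7.33% against 2.59%). In these lists 0 members passed when adjusted over the list alone, and 0 of the 3 lists passed without the testes of pigs 5983 and 5990, left out after their values were seen. With 2 surrogate variables the spermatid and Sertoli medians were -0.096 and -0.12 and neither passed (camera adjusted p = 0.534 for both). The spermatid list also lost its call with sire family (0.26, 0.0560), and the Sertoli and mitochondrial lists in the unnumbered libraries (-0.44 and -0.70, 0.0923 and 0.329). The number of lists that passed was 7 without the set term and 1 in the unnumbered libraries. ALB, the albumin of liver, had the smallest p on the negative side with -9.36 ± 2.17. It stood at 1598 CPM in the High ASI control testis of pig 5990, which held liver transcripts, at 66.9 in that of pig 7863 and at no more than 9.65 in the others. ALB was followed by SLC4A4 (-1.94 ± 0.52) and PLA2R1 (-1.64 ± 0.49). PAX1 (1.59 ± 0.45), ZNF276 (0.81 ± 0.23) and RADIL (0.75 ± 0.23) led the positive side. Of 12714 genes edgeR and DESeq2 called 0, with 488 at an unadjusted p under 0.05 in edgeR.

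In liver, CEBPA (ENSSSCG00000002866), a transcription factor of the hepatocyte, was higher in High than in Low ASI pigs. It averaged 12.5 ± 3.63 CPM (SD, n = 13) against 5.71 ± 2.02 CPM (SD, n = 11), was above the Low ASI median in 13 of 13 High ASI pigs and rose by 1.15 ± 0.20 (log2, SE; edgeR adjusted p = 0.0134). A further 2 genes without a symbol passed among the 12648 tested, ENSSSCG00000027377 with 2.19 ± 0.35 and ENSSSCG00000030262 with -1.34 ± 0.22 (adjusted p = 0.0110 for both), and 2999 genes had an unadjusted p under 0.05. Another 720 genes had an adjusted p between 0.05 and 0.1, 522 positive and 198 negative, so the count was unstable: DESeq2 called 755 (532 positive) and edgeR without the liver of pig 7863, left out after its values were seen, 713 (516 positive), both including the 3 genes. With sequencing lane or sire family as a factor, with 2 surrogate variables, and in voom with the sow as a block it was 0, with 1187, 1289, 1092 and 3066 genes at an unadjusted p under 0.05. The fold of CEBPA was then 0.98, 1.01, 0.86 and 1.17. The number of genes called was 0 without pig 5982 and 515 without pig 7864, 174 without 5980, 122 without 7869, 40 without 9859, 9 without 3918, 8 without 8078 and 5 without 5986, 7005 or 8079.

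Between High and Low ASI liver 5 lists passed camera, and 0 with an estimated correlation. With the preset correlation 10 passed with sire family as a factor and 10 with 2 surrogate variables. Genes of oxidative phosphorylation were positive in 24 of 24 members with a median of 0.40 (camera adjusted p = 1.74e-07; adjusted p = 0.915 with an estimated correlation), 14 of them past the threshold when adjusted over the list alone. The complex I subunits NDUFA10, NDUFV1 and NDUFB10 stood at 0.67 ± 0.18, 0.56 ± 0.15 and 0.69 ± 0.19 (log2, SE). Fibroblast, stellate cell and matrix genes were negative in 16 of 19 with a median of -0.80 (6.19e-05 and 0.915), 9 of them past the threshold over the list alone, such as the collagens COL3A1 at -1.0 ± 0.31 and COL5A2 at -0.77 ± 0.21, and LOX, which crosslinks them, at -1.45 ± 0.46. Cell cycle genes were negative in 17 of 18 (median -0.59; 4.77e-04 and 0.915), 7 of them over the list alone, with BUB1B, of the spindle checkpoint, at -1.56 ± 0.30 and TOP2A, topoisomerase II alpha, at -0.73 ± 0.19. Ribosomal protein genes were positive in 17 of 17 (median 0.35; 6.19e-05 and 0.915; 0 over the list alone), RPS3 at 0.41 ± 0.16. Hepatocyte markers were positive in 14 of 19 (median 0.19; 0.0113 and 0.915), 3 of them over the list alone, namely CEBPA, APOE at 0.62 ± 0.16 and APOC3 at 0.60 ± 0.19. With 2 surrogate variables the medians were 0.092 for oxidative phosphorylation, -0.41 for matrix genes, 0.083 for hepatocyte markers and -0.0096 for ribosomal protein genes, which lost the call (camera adjusted p = 0.912). With lane as a factor the hepatocyte median was 0.11 and the call was lost (camera adjusted p = 0.0501). For these 5 lists fry gave adjusted p from 0.231 to 0.313. Lists of cytochrome P450s, cholesterol biosynthesis, bile acids and fatty acid synthesis did not pass camera (adjusted p = 0.725, 0.651, 0.749 and 0.661). The liver enzymes of skatole and steroid breakdown did not pass the test: CYP2E1 stood at 0.03 ± 0.32, CYP1A2 at 0.04 ± 0.35, CYP2A19 at -0.50 ± 0.79 and AKR1D1 at -0.55 ± 0.36. The sign of the first 2 turned under several settings, and AKR1D1 stood at 0.18 with 2 surrogate variables.

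**Figure D3:**
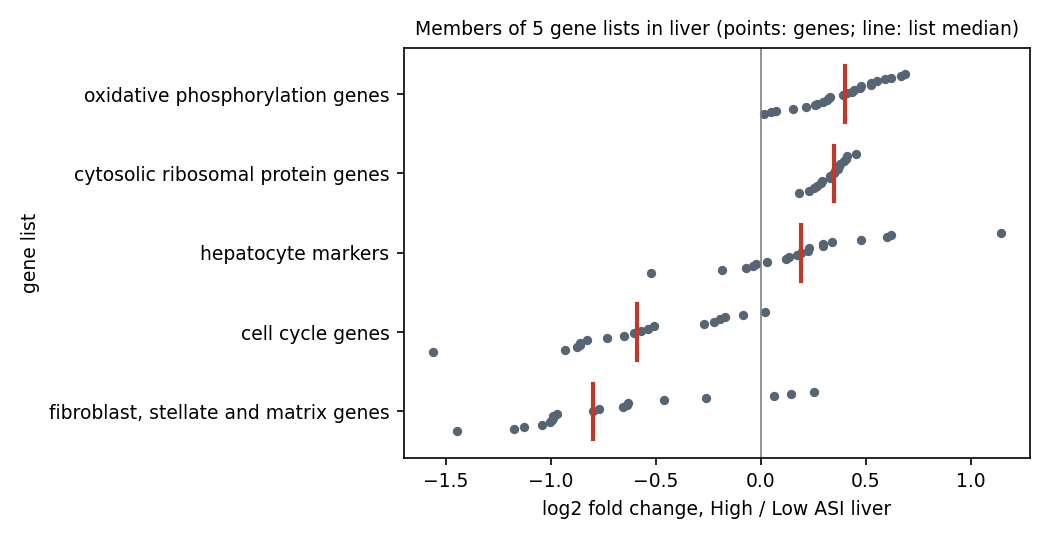
Log2 fold changes between High and Low ASI liver (x axis) of the members of the 5 gene lists that passed camera, with 1 point per gene and a line at each list's median (13 High and 11 Low ASI livers). The medians are 0.40 for oxidative phosphorylation, 0.35 for ribosomal protein genes, 0.19 for hepatocyte markers, -0.59 for cell cycle genes and -0.80 for fibroblast and matrix genes.

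In liver, the chicory diet was compared with the control diet in 12 pigs each. Markers of macrophages and Kupffer cells were positive in 13 of 13 members with a median of 0.40 (camera adjusted p = 8.97e-09; adjusted p = 0.144 with an estimated correlation), 5 of them past the threshold when adjusted over the list alone. C1QA stood at 0.56 ± 0.17 (log2, SE), CD68 at 0.56 ± 0.19 and CSF1R at 0.52 ± 0.19. Bile duct markers were negative in 6 of 7 with a median of -0.58 (6.25e-04 and 0.152), 3 of them over the list alone, with SOX9 at -0.72 ± 0.25 and ANXA4 at -0.34 ± 0.12. Bile acid genes were negative in 13 of 17 (median -0.22; 0.0210 and 0.633), 1 of them over the list alone, CYP27A1, the sterol 27-hydroxylase, at -0.61 ± 0.18, while CYP7A1, the rate-limiting enzyme of bile acid synthesis, stood at -0.98 ± 0.50. Cholesterol biosynthesis genes were negative in 17 of 21 (median -0.17; 0.00538 and 0.685). Fatty acid synthesis genes were negative in 14 of 17 (median -0.23; 0.0120 and 0.633), ACACA at -0.42 ± 0.23. Genes of the mitochondrial genome were negative in 13 of 13 (median -0.29; 0.00167 and 0.685), ND4L at -0.62 ± 0.25. Endothelial markers were positive in 9 of 10 (median 0.23; 6.25e-04 and 0.633), ROBO4 at 0.50 ± 0.21. Ribosomal protein genes were positive in 17 of 17 (median 0.15; 0.00308 and 0.736), RPS28 at 0.28 ± 0.16. Oxidative phosphorylation genes were positive in 20 of 24 (median 0.10; 0.0168 and 0.805), UQCRC1 at 0.18 ± 0.14. In the lists from cholesterol onwards 0 members passed over the list alone. The bile acid list lost its call with 2 surrogate variables (median -0.073, camera adjusted p = 0.331). The oxidative phosphorylation and ribosomal lists lost theirs with lane as a factor (0.050 and 0.084, with 0.302 and 0.0763) and with sire family (0.081 and 0.097, with 0.130 and 0.0712). The oxidative phosphorylation list also lost it without the liver of pig 7863 (0.070, 0.124). CYP2E1 stood at 0.46 ± 0.32, CYP1A2 at 0.24 ± 0.35, CYP2A19 at 0.43 ± 0.79 and NQO1 at -0.13 ± 0.32. CYP2A19 turned to -0.060 with lane as a factor, and NQO1 to 0.036 without pig 3918 and 0.10 without pig 7864. Of 12648 genes edgeR and DESeq2 called 0, with 605 at an unadjusted p under 0.05 in edgeR, led by RBM19 (0.48 ± 0.12), TMEM204 (0.61 ± 0.17) and ADORA3 (0.55 ± 0.16) against REPS2 (-0.89 ± 0.20), CABYR (-0.87 ± 0.23) and ZNF182 (-0.42 ± 0.12).

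The relation of liver genes to androstenone was tested as the same slope. Oxidative phosphorylation genes were positive in 23 of 24 members with a median of 0.12 (camera adjusted p = 1.25e-05; adjusted p = 0.874 with an estimated correlation), NDUFV1 at 0.21 ± 0.07 (log2 per log2 unit, SE). Ribosomal protein genes were positive in 17 of 17 (median 0.11; 5.58e-04 and 0.874), RPLP1 at 0.17 ± 0.09. Hepatocyte markers were positive in 16 of 19 (median 0.10; 0.00245 and 0.874), with APOE at 0.25 ± 0.07 and CEBPA at 0.38 ± 0.12, both past the threshold when adjusted over the list alone. Genes of fatty acid oxidation and of PPARA, its nuclear receptor, were positive in 17 of 21 (median 0.06; 0.0200 and 0.874), with CREB3L3 at 0.21 ± 0.07 and ACAA1 at 0.17 ± 0.06. Fibroblast and matrix genes were negative in 16 of 19 (median -0.27; 5.58e-04 and 0.874), LOX at -0.62 ± 0.21. Cell cycle genes were negative in 15 of 18 (median -0.13; 0.0112 and 0.874), BUB1B at -0.51 ± 0.16. In 5 of these 6 lists 0 members passed over the list alone. With lane as a factor the oxidative phosphorylation, ribosomal, hepatocyte and fatty acid oxidation lists lost their calls (medians 0.036, 0.012, 0.061 and 0.044, camera adjusted p = 0.222, 0.574, 0.0965 and 0.0650). With 2 surrogate variables the ribosomal list did (0.021, 0.334), and the oxidative phosphorylation and matrix medians were 0.036 and -0.11. With sire family the medians of fatty acid oxidation and cell cycle genes were larger, 0.15 and -0.22 (5.96e-07 and 7.56e-04), and 11 lists passed. CYP1A2 stood at -0.16 ± 0.15, AKR1D1 at -0.15 ± 0.15, CYP2E1 at -0.11 ± 0.14 and CYP2A19 at -0.13 ± 0.37. AKR1D1 turned to 0.067 with 2 surrogate variables and CYP2A19 to 0.037 without pig 9859. Of 12648 genes edgeR called 0 and DESeq2 37, with 1638 at an unadjusted p under 0.05 in edgeR, led by WDR5 (0.29 ± 0.06), TRNP1 (0.83 ± 0.18) and NR0B2 (0.52 ± 0.12), a repressor of bile acid synthesis, against MCTP1 (-0.54 ± 0.12), GBP1 (-0.49 ± 0.11) and ARHGEF6 (-0.34 ± 0.08).

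Livers of the 9 pigs with skatole above 0 were compared with those of the 15 pigs at 0. Of the 9 pigs 8 were High ASI, against 5 of the 15, and the fit had no ASI term, so skatole and ASI group overlap in this comparison. All 4 livers of lane 7, from sires with EBV of 0.26 to 0.36, had skatole above 0. The fit had no term for lane or sire family, so these overlap with skatole too. Genes of the mitochondrial genome were positive in 13 of 13 members with a median of 0.80 (camera adjusted p = 7.56e-07; adjusted p = 0.981 with an estimated correlation), 9 of them past the threshold when adjusted over the list alone, among them CYTB at 0.94 ± 0.26 and COX3 at 0.94 ± 0.29 (log2, SE). Nuclear genes of oxidative phosphorylation were positive in 22 of 24 (median 0.34; 1.67e-06 and 0.981), NDUFB10 at 0.63 ± 0.23. Ribosomal protein genes were positive in 17 of 17 (median 0.25; 0.00127 and 0.981), RPL4 at 0.27 ± 0.17, with 0 members of either past the threshold over the list alone. The ribosomal list lost its call with lane, sire family and 2 surrogate variables (medians 0.097, 0.13 and 0.0027, camera adjusted p = 0.239, 0.172 and 0.911). The oxidative phosphorylation median was then 0.16, 0.20 and 0.13, and the mitochondrial one 0.40 with sire family. With sire family 8 lists passed and with 2 surrogate variables 5. Of 12648 genes edgeR called 0 and DESeq2 14, with 1557 at an unadjusted p under 0.05 in edgeR, led by GATA6 (0.69 ± 0.14), MRPS27 (0.77 ± 0.17) and PATL1 (0.44 ± 0.10) against NUGGC (-1.12 ± 0.24), DISP3 (-1.22 ± 0.28) and GUCY2C (-1.14 ± 0.27).

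The interaction of ASI group and diet in liver, again positive where chicory minus control was larger in High ASI pigs, was called in 10 lists with the preset correlation and in 0 with an estimated one. Genes of the urea cycle and amino acid breakdown were negative in 23 of 25 members with a median of -0.55 (camera adjusted p = 8.56e-09; adjusted p = 0.113 with an estimated correlation; fry adjusted p = 0.0138), 5 of them past the threshold when adjusted over the list alone, among them ARG1, the arginase, at -1.47 ± 0.33 and CPS1, the first enzyme of the cycle, at -1.45 ± 0.35 (log2, SE). Fatty acid synthesis genes were negative in 15 of 17 (median -0.88; 2.16e-05 and 0.209), 7 over the list alone, with SCD, the stearoyl-CoA desaturase, at -2.34 ± 0.61 and FASN, the fatty acid synthase, at -2.21 ± 0.71. Cholesterol biosynthesis genes were negative in 20 of 21 (median -0.61; 9.09e-06 and 0.379), 6 over the list alone, with MSMO1 at -1.42 ± 0.43 and HMGCS1 at -2.12 ± 0.75. Acute phase genes were negative in 12 of 14 (median -1.0; 9.18e-04 and 0.379), 2 over the list alone, ITIH4 at -2.40 ± 0.65. Cytochrome P450 and phase I genes were negative in 11 of 14 (median -0.44; 0.00510 and 0.379), 2 over the list alone, with ALDH1A1 at -1.52 ± 0.46. Heat shock and chaperone genes were negative in 17 of 22 (median -0.40; 2.76e-04 and 0.398), 1 over the list alone, HSPD1 at -0.89 ± 0.26. Bile acid genes were negative in 14 of 17 (median -0.56; 0.00470 and 0.370; 0 over the list alone), KLB at -1.89 ± 0.68. Targets of ATF4, a factor of the amino acid stress response, were negative in 9 of 13 (median -0.26; 0.0455 and 0.209; fry adjusted p = 0.0138), 2 over the list alone, CTH at -1.28 ± 0.33. Lymphocyte markers were positive in 17 of 17 (median 0.77; 2.16e-05 and 0.398), CD79B, of the B cell receptor, at 1.26 ± 0.61. Ribosomal protein genes were positive in 17 of 17 (median 0.29; 0.00567 and 0.655), RPLP1 at 0.59 ± 0.39, with 0 members of either past the threshold over the list alone. The ATF4 list lost its call with lane (-0.28, camera adjusted p = 0.0665) and sire family (-0.24, 0.0599). With 2 surrogate variables the ribosomal median turned to -0.080 (0.154), and the lymphocyte and ATF4 medians were 0.44 and -0.42. The cytochrome P450 median was -0.68 with sire family, and 16 lists passed with 2 surrogate variables. Of 12648 genes edgeR called 0 and DESeq2 18, all negative, with 1007 at an unadjusted p under 0.05 in edgeR. ACSL3 (-1.81 ± 0.37) and ARG1 were among the genes with the smallest p on the negative side. RNF227 (1.56 ± 0.35), ORAI3 (1.05 ± 0.27) and GAS8 (1.08 ± 0.29) led the positive side.

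Testis and liver of the same 24 pigs differed in 14506 of 15987 genes, 7903 higher in testis and 6603 higher in liver. Higher in testis were KCTD19 and CCNA1, of meiotic germ cells, ACR, the acrosin of the sperm head, and BOLL, an RNA-binding protein of germ cells, with log2 fold changes of 13.90 ± 0.16, 12.04 ± 0.17, 12.74 ± 0.19 and 12.07 ± 0.17 (SE), beside SPMAP2, CCDC83, EYA2, C10orf53, WDR88 and FAM170B between 11.47 and 13.31. Higher in liver were SLCO2B1, an uptake transporter, at -7.10 ± 0.13, HSD11B1, which activates glucocorticoids, at -6.74 ± 0.14 and GCKR, which binds glucokinase, at -5.29 ± 0.10, beside ORMDL3, HAPLN3, FOXRED1, PDZK1, NDRG2 and MMP19 between -8.96 and -4.74. The adjusted p of these genes lay between 7.63e-54 and 5.80e-43 (edgeR). Of the 38 lists tested 26 passed camera, and 10 of them with an estimated correlation. Meiotic spermatocyte genes rose in 17 of 18 members with a median of 8.14 (adjusted p = 0.0279 with an estimated correlation), with SYCP3, of the synaptonemal complex, at 9.12 ± 0.17 and DMC1, the meiotic recombinase, at 10.85 ± 0.28. The other 9 were lower in testis. Hepatocyte markers were lower in 19 of 19 (median -11.14), HNF4A at -8.98 ± 0.22, fatty acid oxidation genes in 21 of 21 (median -4.03), ACAA1 at -5.45 ± 0.14. Urea cycle genes were lower in 24 of 25 (median -6.67), CPS1 at -8.59 ± 0.22, bile acid genes in 17 of 17 (median -7.53). Cytochrome P450 genes were lower in 14 of 14 (median -6.25), CYP2E1 at -9.87 ± 0.37, nuclear receptors in 18 of 22 (median -2.51), NR1I2, the pregnane X receptor, at -8.31 ± 0.18. Glucose metabolism genes were lower in 16 of 19 (median -3.37), GYS2 at -11.74 ± 0.33. These 7 lists had adjusted p = 0.0279 with an estimated correlation. Macrophage markers were lower in 13 of 13 (median -5.90) and the growth hormone and IGF axis in 11 of 12 (median -2.78), IGFBP1 at -9.34 ± 0.44 (0.0406 for both). Spermatid genes, 24 of 24 called with a median of 12.92, had adjusted p = 0.101 with an estimated correlation.

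The ASI difference itself was compared between the tissues in the 24 pigs, positive where High minus Low was larger in testis. ENSSSCG00000030262 passed as the 1 call among 15987 genes with 1.48 ± 0.28 (log2, SE; edgeR adjusted p = 0.0421; DESeq2 called 36), and 2691 genes had an unadjusted p under 0.05. The fit with the pig number as a block called 0. With the testis library set as a term, added after the values were seen, edgeR called 0 with 2134 genes at an unadjusted p under 0.05, and the smallest adjusted p was 0.0555. Ribosomal protein genes were negative in 17 of 17 members with a median of -0.51 (camera adjusted p = 3.89e-12; adjusted p = 0.577 with an estimated correlation), 12 of them past the threshold when adjusted over the list alone, RPLP1 at -0.72 ± 0.26. Oxidative phosphorylation genes were negative in 22 of 24 (median -0.46; 6.66e-12 and 0.577), 10 over the list alone, NDUFV1 at -0.70 ± 0.19. Fibroblast and matrix genes were positive in 18 of 19 (median 1.04; 2.57e-06 and 0.810), 10 over the list alone, with PDGFRB at 1.29 ± 0.37. Cell cycle genes were positive in 16 of 18 (median 0.61; 0.00740 and 0.836), 4 over the list alone, KIF11 at 0.99 ± 0.29. Endothelial markers were positive in 10 of 10 (median 0.61; 0.0148 and 0.836), 3 over the list alone, KDR, the VEGF receptor, at 1.17 ± 0.35. Immediate early genes were positive in 16 of 17 (median 0.56; 0.0148 and 0.836), NR4A3 at 1.23 ± 0.48. Spermatid genes were negative in 19 of 24 (median -0.94; 0.00139 and 0.836), AKAP4 at -2.10 ± 0.72, genes that took 0.00114% to 0.00357% of liver reads. In these 2 lists 0 members passed over the list alone. In the pigs with a numbered testis library the immediate early median turned to -0.30, the matrix and cell cycle lists lost their calls (0.32 and 0.28, camera adjusted p = 0.808 and 0.104), and the ribosomal and oxidative phosphorylation medians were -0.18 and -0.20, with 12 lists past camera. Without pigs 5990 and 7863 the endothelial and immediate early lists lost theirs (0.39 and 0.49, 0.143 for both), as with the set as a term (0.49 and 0.34, 0.0524 and 0.190).

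The diet difference was compared between the tissues in the same way. Of 15987 genes 7 fell in testis relative to liver with chicory (edgeR adjusted p = 0.0423 for each; DESeq2 called 13): TTR, the transthyretin of plasma, with -6.58 ± 1.27 (log2, SE), HRG with -5.43 ± 1.13, ADH4, an alcohol dehydrogenase, with -5.36 ± 1.13, C8A, of the complement attack complex, with -5.36 ± 1.12, SERPIND1, heparin cofactor II, with -4.84 ± 1.01, and ENSSSCG00000017704 and ENSSSCG00000030522, without a symbol, with -6.09 ± 1.23 and -5.40 ± 1.11. Hepatocyte markers were negative in 17 of 19 members with a median of -1.43 (camera adjusted p = 7.45e-04; adjusted p = 0.698 with an estimated correlation), 11 of them past the threshold when adjusted over the list alone. Endothelial markers were negative in 10 of 10 with a median of -0.71 (1.82e-09 and 0.144), 2 over the list alone, with LYVE1 at -1.19 ± 0.32 and STAB1 at -0.62 ± 0.28. Without pigs 5990 and 7863 the hepatocyte median was -0.22 and the call was lost (camera adjusted p = 0.871), and with the pig number as a block it was -0.77, with 6 lists past camera. The endothelial list lost its call in the pigs with a numbered testis library (-0.82, 0.0601), where the hepatocyte median was -3.38 and 8 lists passed. The count of genes was 0 with the pig number as a block. It was 0 without pig 5990, whose testis library held transcripts of the liver, and also without any of 16 other pigs, and 12 to 14 without pig 7005, 3918, 9867, 5991, 7863 or 7869. The median fold of the 7 genes was -2.14 without pig 5990 and -5.72 to -5.33 without any other. At an unadjusted p under 0.05 there were 586 genes. With the testis library set as a term, added after the values were seen, edgeR called 14 genes, the 7 among them, and 5 lists passed camera.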

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

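The tests chosen after their result was seen were the 2 counts of splits for the ASI groups in liver, the tests of mixed-in liver RNA and of the pig's own liver for pig 5990, the spread put on the cholesterol medians, the comparison of pig 5990 with the other pigs left out, and the liver list medians with lane or axis, while the splits by sire family and the use of counts at an unadjusted p under 0.05 where 0 genes were called were chosen after the main fits but before those splits were run.

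Libraries that stood apart from their group were found by comparing the gap to the nearest library with the range of the group, in 60 sets of values, of which chance alone would pick 3; 8 were picked. The liver of pig 7863 had 2.01 reads outside genes per read in a gene (others of its group 0.206 to 0.394). Mitochondrial transcripts took 14.4% of reads in the High ASI control testis of pig 5990 (others 1.62% to 7.11%), 17.5% in the Low ASI chicory testis of pig 5983 (1.93% to 4.94%) and 15.8% in the Low ASI control testis of pig 5982 (1.56% to 7.04%). The libraries of pigs 5990 and 5982 are numbered, a set that took 5.41% to 15.8% (median 7.33%). The unnumbered libraries without pig 5983 took 1.56% to 5.23% (median 2.59%), so the groups compared here mix 2 sets that differ in this share. Spermatid genes took 0.529% of reads in the testis of pig 5983 (3.42% to 4.92%). The liver-restricted genes stood at 0.995% of their liver level in the testis of pig 5990 (0.00322% to 0.0379%, and 0.00572% to 0.0379% in the other numbered testis libraries). ENSSSCG00000021574 reached 1.84 log2 CPM in the High ASI chicory testis of pig 8078 (others at most -2.49) and 2.06 in the High ASI control testis of pig 7863 (others -3.63, at 0 reads).

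Effects that differed between groups were found by interaction tests. The ASI by diet interaction was called in 3 lists in testis and in 10 in liver, and the ASI difference between tissues in 7 lists and in ENSSSCG00000030262 (1.48). The diet difference between tissues was called in 2 lists and in TTR (-6.58), ENSSSCG00000017704 (-6.09), HRG (-5.43), ENSSSCG00000030522 (-5.40), ADH4 (-5.36), C8A (-5.36) and SERPIND1 (-4.84). With an estimated correlation 0 of these lists passed.

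The higher cholesterol biosynthesis genes of High ASI testis were a median of 0.23 (jackknife SE 0.143), and chance cannot be excluded: 4 of 100 splits of single testes were as large (highest other 0.289), uncorrected for the choice among 22 lists, and 11 of 100 splits within sire families (highest other 0.326). More Leydig cells could bring the same genes, and the Leydig score of 9 markers outside the list differed by 0.26 ± 0.17 (log2, SE); with the score as a term the median was 0.17 (SE 0.133), 19 of 20 members positive, and the unadjusted p with an estimated correlation went from 0.00141 to 0.0976. The uneven spread of the library sets was tested in the 24 unnumbered libraries alone, where the median was 0.18 (SE 0.0958) and 18 of 20 members were positive. Both medians stayed above 0.115, the 50% of the original set beforehand as the limit, but by less than their SE, so both explanations stay open. An effect of the ASI group itself also stays open and was not tested.

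For the broad liver difference between ASI groups 2999 genes had an unadjusted p under 0.05 (at most 2558 in other splits of single livers, 1 of 100 as large) and 3 were called (at most 98, 3 of 100). Within sire families 6 and 4 of 100 splits were as large (up to 4421 genes and 2166 calls), so chance cannot be excluded for the first count. For the 3 calls the share is too near that of the first count to exclude chance either. The high counts could come from a structure of the samples, though the splits do not test for one. Sequencing lane could be one, as 1 lane held 4 High and 0 Low ASI livers: with lane as a factor 1187 genes were left, with list medians (jackknife SE) of -0.76 (0.367) for cell cycle, -0.78 (0.418) for matrix, 0.30 (0.191) for oxidative phosphorylation and 0.22 (0.224) for ribosomal protein genes and 0.11 (0.142) for hepatocyte markers, but lanes also differ in sire EBV (0.2, 0.26 to 0.36 and -0.49 to -0.1 in 3 of them, -0.44 to 0.2 in the other), so lane and sire family overlap, and with sire family as a factor 1289 genes were left. An axis of variation within the groups, 24.5% of their variance, could be another such structure: its score averaged 12.8 ± 36.6 in High and -15.1 ± 26.9 in Low ASI livers (SD, n = 13 and 11; permutation p = 0.0483), and with it as a term 1082 genes were left, CEBPA stood at 0.88 ± 0.18 (log2, SE; edgeR adjusted p = 0.123), and the medians (jackknife SE) were -0.79 (0.348) for cell cycle, -0.42 (0.293) for matrix, 0.10 (0.137) for oxidative phosphorylation and 0.018 (0.102) for ribosomal protein genes and 0.0996 (0.149) for hepatocyte markers. Only the cell cycle median stayed above 50% of its main value by more than its SE, a limit chosen after the values were seen. With an estimated correlation that list had adjusted p = 0.889 with lane and 0.329 with the axis in camera. This is at most weak evidence against lane or axis as its whole cause. With the axis the ribosomal and oxidative phosphorylation medians fell below 50% of their main values, the first by more than its SE. The axis was found within the groups, but its score was computed from the full values and can carry part of the ASI difference. The weights of the genes on the axis correlated with their ASI fold changes (r = 0.669). Lower counts and medians with the axis as a term may therefore be partly built in. For matrix and hepatocyte genes lane and axis, and for ribosomal and oxidative phosphorylation genes lane, cannot be told apart from the ASI group at this spread, and an effect of the ASI group stays open for all 5.

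The liver transcripts in the testis of pig 5990 are consistent with liver RNA or reads mixed into that library: 16 of 19 hepatocyte markers stood within 3-fold of 0.951% of their liver level, with ALB at 16914 reads, and 14 of the 19 were above every other testis. Liver of the same pig is argued against, since over the 75 liver-restricted genes its own liver ranked 5 of 24 (r = 0.385, across genes, which are not independent), and the liver of pig 8078 matched best (r = 0.863, the next 0.464), though the value of r depends on how the profile is computed. Whether a diet effect in testis could lie behind the 7 calls between tissues stays open: 0 stayed without pig 5990, but 0 also stayed without each of 16 of the 23 other pigs, so that count decides nothing, although it met the limit set beforehand. Their median fold went from -5.40 (median SE 1.13) to -2.14 (median SE 0.705) without pig 5990 and lay between -5.72 and -5.33 without each other pig, on genes near 0 reads in the other testes.

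The splits of the samples give the following for the other results. Chance can be excluded for the tissue difference (14506 genes against at most 10370; 1 of 100 splits as large). For skatole in liver, where pigs with skatole were mostly High ASI, 4 of 100 splits of single pigs were as large (1557 genes at an unadjusted p under 0.05 against at most 2006), but 24 of 100 within sire families (at most 4120), so chance cannot be excluded. For breeding value in testis 3 of 100 orders of single pigs called as many genes as the 2 of the real one (at most 19), but pigs of a sire family share the value. When the values were reordered between the 12 families, 11 of 100 orders called as many, up to 360, so chance cannot be excluded. For androstenone in testis 1 order of the pigs called 2505 genes, for a reason that was not tested. Since 5 of 100 orders called as many genes as the 4 of the real one, chance cannot be excluded there either. The same holds for androstenone in liver (1638 against at most 4564; 10 of 100), for ASI in testis (275 against at most 3584; 69), for diet in testis (126 against at most 2025; 97) and in liver (605 against at most 2799; 35), and for the interactions in testis (488 against at most 2435; 56) and liver (1007 against at most 3383; 19), all at an unadjusted p under 0.05. For the ASI difference between tissues 46 of 100 splits called at least 1 gene, up to 340, and for the diet difference 25 called at least 7, up to 316. In each of these the highest split had more than 2 times the real count, at an unadjusted p or in calls as given. What made the counts vary so widely between splits was not tested, and a low real count is easily exceeded.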

How the results depend on the processing

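The fits without pigs 5983, 5990 and 7863, those between tissues with the testis library set as a term, and their list tests were chosen after the data were examined. Of 3563 values of named genes under alternatives, 3417 kept direction and side of the threshold, 75 lost and 43 gained the call and 28 turned; of 464 values of called lists, 323 kept their call, 132 lost it and 9 turned. RLE size factors changed 1 count of calls. Testis depth, 1855174 reads at the lowest, limits genes of low expression. The cause of a change below was not tested unless the setting itself removes pigs or genes.

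Genes called. For liver ASI the count of 3 became 755 in DESeq2, 713 without the liver of pig 7863 and 0 with lane, sire family, the sow block or 2 surrogate variables. For testis androstenone the 4 became 9 without the filter, 0 without the set term or with sire family, 1 (ENSSSCG00000021574) in the unnumbered libraries and 2 with the sow block or on the mg/kg scale. For breeding value the 2 became 10 without the filter, 15 in DESeq2, 0 in the unnumbered libraries and 1 (ENSSSCG00000009374) with the sow block. Counts of 0 became 1 (ENSSSCG00000028731) for testis diet without the filter and in the unnumbered libraries, 1 (ITIH1) for the testis interaction without the filter, 37 in DESeq2 and 1 (ENSSSCG00000023735) in mg/kg for liver androstenone, 14 in DESeq2 for skatole and 18 in DESeq2 for the liver interaction. Between tissues, the pig block and the fit on pigs with a numbered testis library, fewer samples, left 0 genes for the ASI and the diet difference, as did no filter and the fit without pigs 5990 and 7863; RLE left 0 for ASI, DESeq2 called 36 and 13, and with the set as a term 0 were left for ASI and 14 called for diet. The pairing by pig changed no other gene count by over 1.5 times; skatole p was 0.338 in both contrasts above the median of 0.083.

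Lists called. With an estimated correlation 1 stayed for testis ASI, 10 for tissue and 0 elsewhere. Liver ASI went from 5 to 10 with sire family and with 2 surrogate variables, testis diet from 5 to 3 without the set term, 2 in the unnumbered libraries and 8 without pigs 5983 and 5990, liver androstenone from 6 to 11 with sire family, breeding value from 2 to 1 in the unnumbered libraries and with 2 surrogate variables, and skatole from 3 to 8 and 5 with sire family and 2 surrogate variables. The testis interaction went from 3 to 7 without the set term, 1 in the unnumbered libraries and 0 without pigs 5983 and 5990, the liver interaction from 10 to 16 with 2 surrogate variables, the ASI difference between tissues from 7 to 12 in the numbered pigs, and the diet difference from 2 to 6 with the pig block, 8 in the numbered pigs and 5 with the set as a term.

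Leaving out 1 pig at a time moved the count between 0 and 713 for liver ASI, 0 and 6 for testis androstenone, 0 and 4 for breeding value, 0 and 1 for the liver interaction, 0 and 11 for the ASI and 0 and 14 for the diet difference between tissues, and 14415 and 14670 for tissue, and left 0 in the other comparisons. For androstenone it was 0 without 5995, 8080 or 8086, 1 without 3923, 5973 or 5976, and 2 without 5974, 5985, 5986, 7858, 7869, 8078, 8079, 8094 or 8095. For breeding value it was 0 without 7863, 8080 or 8095, 4 without 5983 and 1 without 3908, 3918, 5973, 5982, 5985, 5988, 5990, 7005, 7864, 8072, 8077, 8078, 8094, 9859 or 9867. For the ASI difference it was 0 without 5973, 5982, 5985, 5995, 7863, 8072, 8078, 8080, 8086 or 9859, 2 without 5974, 7005, 8079 or 9867, 3 without 3918 or 5990, 4 without 8094, 5 without 8095 and 11 without 5980. For the diet difference it was 12 to 14 without 7005, 3918, 9867, 5991, 7863 or 7869, and 0 without 5973, 5974, 5976, 5980, 5982, 5985, 5986, 5990, 5995, 7864, 8072, 8078, 8079, 8080, 8094, 8095 or 9859.

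Values that turned (log2). Liver ASI: CYP2E1 -0.14 with sire family, -0.058 with the sow block and -0.025 with 2 surrogate variables, CYP1A2 -0.12 with the sow block, RPLP2 and with it the ribosomal list -0.0096, and AKR1D1 0.18, with 2 surrogate variables; leaving out 1 pig moved CYP2E1 from -0.083 to 0.15 and CYP1A2 from -0.14 to 0.18. Liver diet: CYP2A19 -0.060 with lane, and NQO1 from -0.35 to 0.10 leaving out 1 pig. Androstenone: in testis ND2 -0.030, ND4 -0.039, ATP8 -0.073 and the mitochondrial list -0.039 with sire family, and on ranks ND4 -8.88e-04 and ATP8 -0.00218; in liver AKR1D1 0.067 with 2 surrogate variables, and CYP2A19 from -0.30 to 0.037 leaving out 1 pig. Breeding value, unnumbered libraries: FBN1 0.17, and the matrix list, median -0.055, turned in its test. Testis interaction: without the set term COX2 0.19, COX3 0.064, ND3 0.085 and their list 0.27; without pigs 5983 and 5990 0.067, 0.078, 0.027 and 0.11; with sire family COX2 0.051, COX3 0.13 and the list 0.14; TF 0.64 in the unnumbered libraries; spermatid list -0.10 with 2 surrogate variables. Liver interaction: ribosomal list -0.080 with 2 surrogate variables. ASI between tissues, numbered pigs: KLF4 -0.28, IER3 -0.67, EGR1 -0.19 and the immediate early list -0.30. Diet between tissues, without pigs 5990 and 7863: AHSG 0.34 and APOC3 0.37.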

Other observations

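The test of 1 gene in both tissues with its limit of 3 reads, and the relation of the liver axis to the mitochondrial share, were chosen after values were seen. ENSSSCG00000021574, negative against androstenone in testis, was seen in part of the pigs in both tissues. Of the 24 pigs with both tissues, 6 had more than 3 reads in testis and in liver, 1 in testis alone, 0 in liver alone and 17 in neither (Fisher's exact p = 5.2e-05). The highest testis count was 62 reads.

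In the liver fit with the axis of variation within the groups as a term, 9 lists passed camera between the ASI groups with the preset correlation and 0 with an estimated one (adjusted p from 0.329 to 0.697 for the 9). With that term, lymphocyte markers had a median of -0.39 between High and Low ASI livers (camera adjusted p = 8.21e-04, against 0.791 without the term), antigen presentation genes -0.26 (0.0421 against 0.651), immediate early genes -0.36 (0.0117 against 0.248), fatty acid oxidation genes 0.16 (0.00736 against 0.0854) and urea cycle genes 0.20 (0.0234 against 0.248). With an estimated correlation the adjusted p was 0.694 for the first 4 of these and 0.697 for urea cycle genes. The axis score was compared with the mitochondrial share of reads, with r = 0.501 and rho = 0.547 (permutation p = 0.0127 and 0.0062, adjusted p = 0.0380 for r over 3 relations; r = 0.589 without the 2 farthest livers), and r = 0.674 and 0.433 within the lanes of 8 livers (exact permutation p = 0.0754 and 0.287).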
